A study of Rattus norvegicus with 132 samples.

How the data were processed

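Kidney tissue of rats was profiled with the GeoMx digital spatial profiler, in which probes hybridised to a formalin-fixed, paraffin-embedded section carry barcodes that are released by light from a chosen region of interest (ROI) and counted by sequencing. Per the labels, 132 ROIs were chosen by hand in 4 kidney areas (glomeruli, cortex, corticomedullary junction and medulla) of sections from 3 rats in each of 4 groups (Sham, HS, RM and RM-HS), hybridised with the mouse whole-transcriptome probe set and sequenced on a NovaSeq. The submitters' processing notes name the builds GRCh38 and hg38, which are human. How these entered the processing is not given in the sources used here, and no coordinate is printed. Gene names are the mouse symbols of the deposited table, of which 8442 of 9271 also occur as symbols in the RefSeq gene table of the rat (assembly GRCr8), as do 8056 of the 8827 genes tested. A further 172 of the 9271 occur there as synonyms.

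The deposited table holds 9272 features (9271 genes and 1 negative-probe value) for 132 ROIs, and its values are signal normalized by the authors to the upper quartile (Q3): the 75th percentile of each ROI was 58.1573. Multiplying each ROI by 1 factor gave whole numbers for 100% of its values, within 1e-04 reads, in all 132 ROIs, so that whole reads could be recovered for tests on counts. The software behind the table is not given in the sources used here. No value was 0. No pair among 8646 pairs of ROIs was identical, and the highest correlation of a pair was 0.977 on the log2 scale.

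Wells named in the sample titles place 90 ROIs on plate C, 41 on plate E and 1 on plate A. The ROIs of each group were put into 3 runs of consecutive wells, 12 in all, numbered here by their order, each run passing once through the areas sampled. Some runs skip a well, runs of 1 group can follow each other directly, and RM-HS run 3 is in 2 pieces: Sham run 1 lies between its medulla wells and its other wells. The labels do not say that a run is an animal. They do not tie ROIs to animals either, so that up to 9 ROIs of a group and area come from 3 animals and some share an animal: p-values over ROIs are therefore too small, and this holds for each test in the text. Every HS ROI was on plate E, together with a single Sham run, so that HS was separated from the plate by 12 Sham ROIs (3 per area). All RM and RM-HS ROIs but 1 were on plate C.

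Genes were kept when their value was over 2 times the negative probe in at least 10% of ROIs, which left 8827 of 9271 (444 left out). A stricter filter of 50% kept 4233. The ROI on plate A (RM, glomeruli) was left out of the fit of 131 ROIs, since 1 ROI cannot be told apart from its plate. Values were log2-transformed after adding 1. In limma 3.58.1 (R 4.3.3), 16 means of group and area and 1 plate term were fitted, with the well run as a random block (consensus correlation 0.132, statmod 1.5.0), moderated variances with a trend, and Benjamini-Hochberg adjustment over the 8827 genes. Genes past an adjusted p of 0.05 (two-sided) were called. The plate term was past that threshold for 52 genes. Each injury was compared with Sham as the average over the 4 areas and within each area. RM-HS was compared with RM and with HS. The interaction of RM and HS tested whether the RM-HS effect differed from the sum of the separate effects. An F test asked whether an effect differed between areas, and areas were compared within Sham. Labels give the aim of the series as region-specific transcription in trauma-induced acute kidney injury and state no test.

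The model, the threshold, 30 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, among called genes, the 5 largest rises and 5 largest falls of each injury against Sham and 2 of each in every area. For the other comparisons of groups it takes the 6 largest rises and 6 largest falls, with 2 of each in every area for RM-HS against RM. It takes the 5 lowest p for each F test, the 5 largest rises between areas of Sham, and up to 4 called members of each list in the average (with no call, up to 2 with the lowest p). Havcr1 and Slc34a1 were always named. Lcn2 and Hmox1 were on that list too and are not analysed here. A few other genes that the rule takes are not reported here. List members named for a single area, and genes named from fits added later, were chosen after their values were seen. Lists were tested against all other genes with cameraPR of limma (preset correlation 0.01), adjusted over the 30 lists, and again with a correlation estimated from the residuals. Counts without a single well run are given where they lay over 1.5 times from the count with all runs. Counts "adjusted over the list alone" use the members of 1 list as the family. A list member is counted as risen or fallen when it passed the threshold over all genes. No list was tested with a single well run left out.

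Alternatives were a pseudocount of 5, no filter and the stricter filter, quantile normalization, subtraction of the negative probe, no plate term, 1 plate alone, no block, 1 mean per well run and area, the plate A ROI kept, each well run left out, each of the 5 HS glomerular ROIs left out, and edgeR 4.0.16 (quasi-likelihood test, trimmed-mean scaling, no block) on the recovered reads. Added after the data were seen were 5 more: a limma fit in which each area has its own spread (variance weights by area, consensus correlation 0.213), a fit without 2 Sham glomerular ROIs of fewest reads, edgeR on reads summed per well run and area, a fit with the 2 pieces of RM-HS run 3 as separate blocks (13 blocks, consensus correlation 0.129), and HS against the 2 other Sham runs, without Sham run 3 and the plate term.

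Recovered reads ranged from 17894 to 2305964 per ROI (median 938179), with medians of 819487 in cortex, 1144390 at the corticomedullary junction, 93104 in glomeruli and 1309721 in medulla. Median upper quartiles were 83 reads in cortex and 11 in glomeruli, so that most glomerular genes rest on few reads. Whether duplicate reads were removed is not given in the sources used here, and no counting interval is printed.

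The tests were tested on simulated data of 8827 genes with the design and depths of the series, in which 100 genes changed 1.5-fold and 100 changed 3-fold. For the RM average, limma recovered 85 and 100 of them and called 21 unchanged genes. For RM in glomeruli it recovered 56 and 100 and called 867 unchanged genes, and in RM-HS glomeruli, where no gene was changed, it called 761. With a spread for each area these became 83, 100 and 15 for the RM average, 9, 91 and 14 for RM glomeruli, and 0 for RM-HS glomeruli. edgeR on reads recovered 96 and 100 and called 883 unchanged genes for the RM average, and 31, 97 and 216 for RM glomeruli. A changed list was called and 0 of 20 random lists.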

Results

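Gene expression was measured by spatial profiling in 132 ROIs of rat kidney from 4 groups of 3 animals: Sham, RM, HS and RM-HS. The labels do not expand RM and HS. In trauma-induced acute kidney injury they commonly stand for rhabdomyolysis, the breakdown of skeletal muscle, and hemorrhagic shock, a reading not stated in the labels. Sham had 9 ROIs in each of cortex, corticomedullary junction, glomeruli and medulla. RM had 9, 8, 9 and 9 in that order (8 glomerular ROIs in the fit), HS had 9, 9, 5 and 6, and RM-HS had 9, 8, 6 and 9. Recovered reads ranged from 17894 to 2305964 per ROI. Glomerular ROIs held a median of 93104 reads against 819487 in cortex, 1144390 at the junction and 1309721 in medulla, and HS held fewer than Sham in each area: 414439 against 526350 in cortex, 561505 against 1089345 at the junction, 49405 against 79136 in glomeruli and 316815 against 1042530 in medulla. On plate E, which held all HS ROIs, the Sham medians were 225787, 647845, 20345 and 789262 in the same order. Within that plate HS held more than Sham in cortex and glomeruli. The negative probe, a measure of background, had a median of 27.3 in cortex, 22.0 at the junction, 17.1 in glomeruli and 19.6 in medulla. Changes are given as log2 fold changes ± SE from limma.

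Kidney areas of Sham rats were compared first, as a check of the area labels. At the corticomedullary junction, Slc7a13, an amino acid transporter of the straight proximal tubule, exceeded cortex by 4.80 ± 0.17 and Slc3a1, a subunit of the cystine transporter, by 3.63 ± 0.19. Gclm, of glutathione synthesis, exceeded it by 4.21 ± 0.22, as did Aadat (3.97 ± 0.18) and Mat2a (3.32 ± 0.14), enzymes of amino acid metabolism. In glomeruli, the semaphorin gene Sema3g exceeded cortex by 3.48 ± 0.19, with Sparc, Smad6 and Prg4 next (2.04, 2.02 and 1.78). In medulla, the loop of Henle cotransporter gene Slc12a1 rose by 4.26 ± 0.20, Spp1 (osteopontin) by 4.01 ± 0.28, Ppp1r1a by 2.39 and Slc5a3 (myo-inositol uptake) by 2.38. Of 13 podocyte markers measured, 11 were higher in glomeruli and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 9.45e-08 with an estimated correlation), and 3 of 8 endothelial markers were higher (adjusted p = 0.0215 with an estimated correlation). Of 9 loop of Henle genes, 7 were higher in medulla (7 and 1 lower adjusted over the list alone; adjusted p = 2.67e-11 with an estimated correlation), while 19 of 24 proximal tubule genes were lower and 1 higher there (adjusted p = 7.11e-06 with an estimated correlation). In limma, 698 genes differed between junction and cortex (613 up, 85 down), 3388 between glomeruli and cortex (245 up, 3143 down) and 1030 between medulla and cortex (564 up, 466 down), over ROIs of which some share an animal. The median gene lay 0.27 below cortex in glomeruli (log2 fold change -0.27), and the glomerular split was 971 up, 1046 down under quantile normalization and 272 up, 109 down in edgeR; with a spread for each area the counts were 1599, 1217 and 2590. Junction against cortex was 733 up, 435 down under quantile normalization and 885 up, 443 down in edgeR, and medulla against cortex gave 535 without Sham 2 and 623 without Sham 3.

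RM against Sham asked which transcripts this injury changed. Averaged over the 4 areas, Spp1, the secreted phosphoprotein osteopontin, rose by 2.86 ± 0.27 (adjusted p = 2.77e-17), and the metallothionein gene Mt2 rose by 2.41 ± 0.17. Thbs1, a matricellular protein gene, rose by 2.36 ± 0.22, the stress-inducible zinc finger gene Zfand2a by 2.21 ± 0.16, and Zfp36, whose protein promotes mRNA decay, by 2.07 ± 0.14. Each of these 5 genes was above the Sham mean of its area in 34 of 34 RM ROIs. Havcr1 (kidney injury molecule 1) rose by 1.37 ± 0.16 (adjusted p = 5.82e-12; above the Sham mean in 27 of 34). The largest falls were Rgs19 (-1.44 ± 0.24), a regulator of G protein signalling above the Sham mean in 1 of 34 ROIs, Zfp609 (-0.99), the ephrin receptor gene Epha3 (-0.97), Smim22 (-0.90) and Snorc (-0.87). Mean log2 signal over the ROIs of Sham runs 1, 2 and 3 was 9.37, 8.77 and 7.43 for Rgs19, 6.45, 6.07 and 5.16 for Zfp609, 6.45, 5.96 and 4.86 for Epha3, 10.1, 9.14 and 9.06 for Smim22 and 5.89, 5.31 and 4.28 for Snorc. Sham run 3, on plate E, was below all 3 RM runs for Rgs19 (7.59 to 7.68), Epha3 (5.06 to 5.42) and Snorc (4.53 to 4.85). Without Sham 1, Smim22 (-0.43, adjusted p = 0.682) and Snorc (-0.58, adjusted p = 0.412) did not pass in limma, nor did Snorc without the plate term (-0.43, adjusted p = 0.237). Slc34a1, the proximal tubule phosphate cotransporter gene, did not pass (0.27 ± 0.19, adjusted p = 0.412).

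Among the fixed lists, 12 of 16 tubular injury and repair markers rose and none fell (13 adjusted over the list alone), led by Spp1, S100a11 (1.69), the stress cytokine gene Gdf15 (1.55) and clusterin, Clu (1.52). Of 22 immediate early genes, which respond within minutes to stimuli, 16 rose (17 adjusted over the list alone), among them Klf6 (1.80), Junb (1.68) and Fosl2 (1.65). Of 16 genes of the NRF2 and oxidative stress response, 8 rose (9 adjusted over the list alone), including Mt2, the autophagy receptor gene Sqstm1 (1.89), Mt1 (1.47) and Gclm (1.39). Heat shock genes rose in 8 of 15 cases (9 adjusted over the list alone), with Dnaja1 at 1.32, Hspa1a at 1.26 and Hsp90ab1 at 1.10. Of 16 genes of the unfolded protein and integrated stress response 6 rose (7 adjusted over the list alone), among them Atf3 (1.51), Atf4 (1.39) and the chaperone gene Hspa5 (1.16). Of 13 p53 targets and cell death genes 6 rose (6 adjusted over the list alone), including Gadd45a (1.70), Gadd45g (1.26) and the survival gene Mcl1 (0.97). Of 15 extracellular matrix genes 6 rose (6 adjusted over the list alone), including Thbs1, the collagen IV gene Col4a1 (1.21), Timp3 (1.17) and Adamts1 (0.97). With an estimated correlation the adjusted p of these 7 lists was 1.42e-08, 7.83e-09, 3.28e-06, 0.00105, 0.00117, 0.000108 and 0.00205, in the order given. The ferritin genes Fth1 (1.68) and Ftl1 (1.62) rose with Cp (0.52) among 12 heme and iron genes (3 adjusted over the list alone; adjusted p = 0.00578 with the preset correlation and 0.0694 with an estimated correlation). Of 19 mitochondrial electron transport genes 6 rose (9 adjusted over the list alone), with Atp5b at 0.84, but that list's call was lost (adjusted p = 0.243 with an estimated correlation). Of 9 loop of Henle genes Ppp1r1a (-0.83) and Slc12a1 (-0.68) fell (4 adjusted over the list alone; adjusted p = 0.0941 with an estimated correlation). Some calls were lost when 1 well run was left out: those of Cp (Sham 1, RM 1 or RM 2), Atp5b and Hspa5 (Sham 1), Slc12a1 (Sham 2 or RM 2) and Hspa1a (RM 2).

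In lists without a call for RM, the hypoxia genes Ndrg1 (0.96), Aldoa (0.58), Pgk1 (0.45) and Hk1 (0.40) rose (4 of 16, 7 rises and 3 falls adjusted over the list alone; adjusted p = 0.197 with an estimated correlation). So did Socs3 (1.02), Cebpb (0.97) and Cebpd (0.67) of 11 cytokine and NF-kB genes, Flt1 (0.60) and Ptprb (0.42) of 8 endothelial markers, Vim (0.58) of 11 mesangial and fibroblast markers, Cd74 (0.70) of 7 macrophage markers, the tissue factor gene F3 (1.02) of 6 complement and coagulation genes and Kl (0.55) of 7 distal tubule genes. The water channel gene Aqp2 fell (-0.61) among 9 collecting duct genes. No member passed among 24 proximal tubule, 15 fatty acid oxidation, 13 podocyte, 4 neutrophil, 6 lymphocyte, 5 interferon, 9 cell cycle, 10 renin-angiotensin, 5 skeletal and cardiac muscle, 5 erythroid, 4 adipocyte and hepatocyte and 4 urothelial genes. In limma, 733 genes passed in the RM average (664 up, 69 down). Within plate C alone 2548 passed (1357 up, 1191 down), and the split was 966 up, 564 down under quantile normalization and 1791 up, 1783 down in edgeR; leaving out a well run gave 294 without Sham 1 and 2232 without HS 3. With 1 mean per well run and area in place of single ROIs, 426 genes passed. The labels do not tie ROIs to animals, so these p-values are too small. Without Sham 1 the calls of Aldoa, Pgk1, Hk1, Flt1, Ptprb, Vim, Cd74, Kl and Aqp2 were lost, some of them also without other runs.

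**Figure D1:**
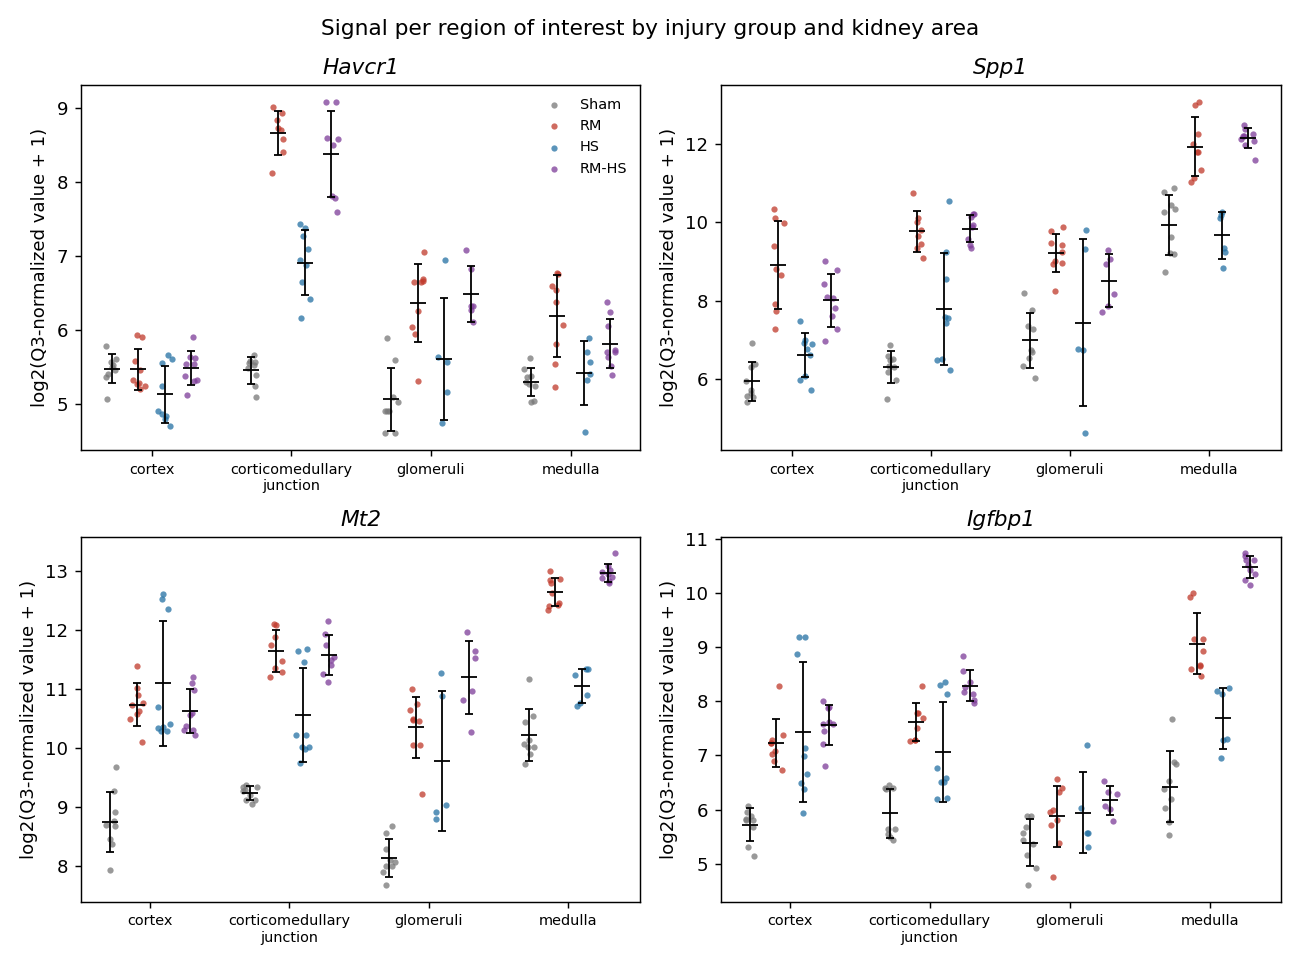
Signal of Havcr1, Spp1, Mt2 and Igfbp1 in each ROI, as log2 of the Q3-normalized value plus 1, by kidney area and colored by group; horizontal bars are means and error bars 1 SD, over 5 to 9 ROIs (RM glomeruli include the ROI left out of the fit). Havcr1 at the corticomedullary junction lay higher in RM and RM-HS than in Sham, with HS between them.

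Areas differed in how RM changed them. Havcr1 at the corticomedullary junction was 43.2 ± 5.24 (SD, n = 9) in Sham and 413 ± 79.2 (SD, n = 8) in RM, a rise of 3.21 ± 0.22, against -0.02 ± 0.22 in cortex, 1.43 in glomeruli and 0.87 in medulla (F test between areas, adjusted p = 4.62e-22). Also among the genes with the lowest p of that test were Zfand2a (3.52 in cortex and 0.51 in medulla), Acly, of fatty acid synthesis (2.34 at the junction and 0.09 in medulla), and Ppp1r1a (-0.36 in cortex and -2.25 ± 0.18 in medulla). In cortex, Zfand2a and Spp1 (3.16) rose most, and Rgs19 (-1.49) and Epha3 (-1.16) fell most. At the junction, Plin2, which coats lipid droplets, rose by 3.75 ± 0.26 and Spp1 by 3.61, while Pck1, of gluconeogenesis, fell (-2.62 ± 0.35) from 469 ± 92.7 (SD, n = 9) to 67.1 ± 25.3 (SD, n = 8), and Rgs19 fell (-1.77). In medulla, Tsc22d1 (2.59) was among the largest rises, and Ppp1r1a and Pyroxd2 (-1.60) fell most. There 5 of 9 loop of Henle genes fell (5 falls and 1 rise adjusted over the list alone), among them Slc12a1 (-1.37), Egf (-1.02) and the potassium channel gene Kcnj1 (-0.80; adjusted p = 0.00082 with an estimated correlation), and 13 of 16 injury markers rose (16 adjusted over the list alone; adjusted p = 1.08e-10 with an estimated correlation). In cortex 8 of 19 mitochondrial genes rose (15 adjusted over the list alone, adjusted p = 0.0177 with an estimated correlation). The list was not tested without Sham 1, and differing Sham runs may be its source. Cortical Rgs19 and Epha3 did not pass without Sham 1 or the plate term.

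In limma 485 genes passed for RM in cortex (465 up, 20 down), 498 at the junction (429 up, 69 down) and 526 in medulla (427 up, 99 down), and 858 genes passed the F test. The median gene at the junction moved by -0.12. Within plate C alone the 3 areas gave 952, 942 and 907 genes, and the F test 1203. Quantile normalization gave 771 up, 361 down in cortex, 543 up, 234 down at the junction and 609 up, 350 down in medulla, and edgeR gave 1202 up, 844 down, 1624 up, 983 down and 1459 up, 936 down. A spread for each area gave 830, 1010 and 1050 genes. Means per well run and area gave 99, 195 and 204, and the F test 107. Leaving out a well run gave 137 without Sham 1, 283 without RM 2, 292 without RM 1 and 789 without HS 3 in cortex, 238 without Sham 1 and 761 without HS 3 at the junction, 292 without Sham 1 in medulla and, for the F test, 468 without RM 1, 506 without RM 2 and 570 without RM 3. Some ROIs share an animal, so these p-values are too small.

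HS against Sham asked which transcripts this injury changed, and 15 genes passed in the average over areas (11 up, 4 down). Igfbp1, an insulin-like growth factor binding protein gene, rose by 1.52 ± 0.26 (adjusted p = 5.26e-05; above the Sham mean in 28 of 29 ROIs), the glucocorticoid-induced leucine zipper gene Tsc22d3 by 1.51 ± 0.21 (25 of 29) and Mt2 by 1.32 ± 0.22 (29 of 29). Olfr761, named for a mouse olfactory receptor, rose by 1.13 ± 0.19 and Sat1, of polyamine breakdown, by 1.09 ± 0.22. Mt1 (0.89), Sqstm1 (0.87), the phosphatase gene Dusp1 (0.80) and, named after their values were seen, Zbtb16 (0.83), Pgls (0.72) and Lmo4 (0.57) also rose. Falls were Arhgap24 (-1.09 ± 0.24), Cyfip2, of actin regulation (-0.98 ± 0.17; above the Sham mean in 2 of 29), the monocarboxylate transporter gene Slc16a7 (-0.86) and the chemokine gene Cxcl12 (-0.75). Arhgap24 was above the mean of all Sham ROIs in 16 of 29 HS ROIs, and its fall is relative to the Sham ROIs of plate E. Without the plate term it (-0.06, adjusted p = 0.893), Cxcl12 (-0.31, adjusted p = 0.168) and Pgls (0.18, adjusted p = 0.441) did not pass, nor did Slc16a7 without RM 3 or without RM-HS 2. Of 100 splits of the same ROIs 68 gave 15 or more genes (highest other 168). These splits put HS labels on both plates, not on plate E alone, and so set no level of chance. Chance among ROIs is not excluded. Havcr1 (0.47 ± 0.21, adjusted p = 0.824) and Slc34a1 (0.02 ± 0.24, adjusted p = 0.999) did not pass. Of 16 NRF2 and oxidative stress genes Mt2, Mt1 and Sqstm1 rose (3 adjusted over the list alone; adjusted p = 4.49e-06 with the preset correlation and 0.0656 with an estimated correlation), and of 22 immediate early genes Dusp1 rose (3 adjusted over the list alone; adjusted p = 0.188 with an estimated correlation). Heme and iron genes (0 of 12 passed, upward) and loop of Henle genes (0 of 9, downward) were called with the preset correlation (adjusted p = 0.0293 and 0.0173), not with an estimated one (adjusted p = 0.188 and 0.188). The other 26 lists were not called. Within plate E alone limma called 0 genes (74 at an unadjusted p under 0.05), edgeR called 122 over both plates, without the plate term 320 passed, and the limma count was 103 without HS 2 and 657 without HS 3. Without HS 3 the 15 genes still passed. Rises were smaller for Mt2 (0.73), Igfbp1 (0.98), Sat1 (0.70), Mt1 (0.59), Zbtb16 (0.53) and Tsc22d3 (66.5% of 1.51). Against the 2 Sham runs of plate C Tsc22d3 was 0.64, Cyfip2 -0.40 and Mt2 1.75. With 1 mean per well run and area 2 genes passed. As plate and injury are told apart by 12 Sham ROIs alone, and ROIs are not tied to animals, these p-values are too small; quantile normalization split the calls 15 up, 12 down.

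By area, HS raised Mt2 in cortex by 2.07 ± 0.26 and Igfbp1 by 1.99 ± 0.31. There Mt2, Mt1 and Sqstm1 of 16 NRF2 genes rose (4 adjusted over the list alone; adjusted p = 0.000443 with an estimated correlation). At the junction, Havcr1 rose by 1.49 ± 0.25 (adjusted p = 0.000227), to 124 ± 35.7 (SD, n = 9), with Ccn2 (1.52) and Thbs1 (1.5), both matricellular genes, while Pck1 (-1.98 ± 0.40) and Cyfip2 (-1.02) fell. Of 16 injury markers there, Havcr1 passed (4 adjusted over the list alone; adjusted p = 0.00234 with an estimated correlation). In medulla, Igfbp1 (1.90) and Tsc22d3 (1.52) rose and Arhgap24 (-1.48) and Cyfip2 (-1.44) fell. Also in medulla, 3 of 19 mitochondrial electron transport genes fell (13 adjusted over the list alone): Atp5b (-1.28), Atp5a1 (-1.20) and Cox8a (-0.87; adjusted p = 0.0284 with an estimated correlation), as did Kcnj1 (-1.10) of 9 loop of Henle genes (5 adjusted over the list alone; adjusted p = 0.0136 with an estimated correlation). Without HS 3 the cortical rises were smaller (Mt2 1.37, Igfbp1 1.16) and Thbs1 at the junction did not pass (0.75, adjusted p = 0.25). Against the 2 other Sham runs alone, without the Sham run of plate E, Igfbp1 in medulla passed in limma (1.39, adjusted p = 0.0203) and Arhgap24 turned to 0.25 (adjusted p = 0.858). Calls were lost there for Tsc22d3 (0.69, adjusted p = 0.327), Cyfip2 (-0.79, adjusted p = 0.0658), Atp5b (0.13, adjusted p = 0.942), Atp5a1 (-0.18, adjusted p = 0.901), Cox8a (-0.04, adjusted p = 0.974) and Kcnj1 (-0.62, adjusted p = 0.4). Without the plate term Igfbp1 and Cyfip2 passed. Calls were lost for Tsc22d3 (0.96, adjusted p = 0.0578), Arhgap24 (-0.45, adjusted p = 0.793), Atp5b (-0.31, adjusted p = 0.905), Atp5a1 (-0.53, adjusted p = 0.672), Cox8a (-0.31, adjusted p = 0.79) and Kcnj1 (-0.90, adjusted p = 0.0578). The calls of these 6 thus rest on the single Sham run of plate E. Ccn2 at the junction did not pass without Sham 2, nor Arhgap24 in medulla without HS 2. HS medulla had no ROI from HS well run 3. Counts in limma were 7 in cortex (7 up, 0 down), 25 at the junction (19 up, 6 down) and 33 in medulla (4 up, 29 down). Within plate E alone they were 0, 0 and 1 (44, 83 and 120 at an unadjusted p under 0.05), and in edgeR 499 (402 up, 97 down), 533 and 334; quantile normalization split cortex 19 up, 4 down and junction 22 up, 15 down. A spread for each area changed the counts to 18, 93 and 258, but 8 of 100 splits of the same ROIs gave as many in cortex (highest other 250) and 7 in medulla (549), so that chance among ROIs is not excluded there under that fit. From 1 mean per well run and area limma gave 0, 0 and 1 (92, 148 and 248 at an unadjusted p under 0.05; edgeR on reads summed in the same way 2, 16 and 5), and without the plate term 184, 114 and 13. Leaving out a well run gave 14 without HS 1 and 146 without HS 2 in cortex, 13 without Sham 2 and 73 without HS 2 or without HS 3 at the junction and 7 without HS 2, 18 without Sham 2, 187 without HS 1 and 354 without HS 3 in medulla. Since ROIs are not tied to animals, these p-values too are too small. The F test between areas passed for 1198 genes (222 within plate E, 261 with 1 mean per well run and area, 0 in edgeR on reads summed in the same way, with 720 at an unadjusted p under 0.05). The lowest p were those of Actg1, a cytoskeletal actin gene (1.12 at the junction and -1.20 in medulla), and of Cenpn, Tceal9, Fxr2 and Gja5, whose glomerular values were -1.64, 1.80, -1.31 and 1.62. The last 4 passed against Sham in glomeruli alone, where 0 genes passed for HS with a spread for each area.

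RM-HS against Sham asked what both injuries changed together. Mt2 rose by 2.63 ± 0.17 (adjusted p = 2.47e-28), Spp1 by 2.50 ± 0.27, Sat1 by 2.47 ± 0.17, Gadd45a by 2.21 ± 0.16 and Igfbp1 by 2.12 ± 0.20, each above the Sham mean in 32 of 32 ROIs. Havcr1 rose by 1.20 ± 0.16 (28 of 32; adjusted p = 2.37e-09) and Slc34a1 did not pass (0.28 ± 0.19, adjusted p = 0.53). The largest falls were Clec2j (-1.31 ± 0.22; above the Sham mean in 0 of 32), Gm20792 (-1.06), Rgs19 (-0.97), the elastin gene Eln (-0.86) and Wdhd1 (-0.85). Without Sham 1, Gm20792 (-0.85, adjusted p = 0.104), Rgs19 (-0.67, adjusted p = 0.56) and Eln (-0.68, adjusted p = 0.313) did not pass in limma, nor did Eln without RM-HS 1 and Rgs19 without the plate term (-0.43, adjusted p = 0.447). Of 16 injury markers 11 rose (12 adjusted over the list alone), including Gdf15 (1.51) and S100a11 (1.26). Immediate early genes rose in 17 of 22 cases (18 adjusted over the list alone), with Zfp36 at 2.10, Btg2 at 1.86, Klf6 at 1.81 and Jun at 1.49. Of 16 NRF2 genes 6 rose (7 adjusted over the list alone), including Sqstm1 (1.73), Mt1 (1.52) and Sod2, a superoxide dismutase gene (1.40). Of 13 p53 targets and cell death genes 6 rose (6 adjusted over the list alone), with Gadd45g at 1.21, Mcl1 at 1.06 and Acsl4 at 0.77. These 4 lists kept adjusted p = 4.87e-08, 3.65e-09, 2.34e-06 and 1.51e-06 with an estimated correlation.

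Smaller groups of RM-HS genes rose as well. They were 5 of 16 unfolded protein response genes (6 adjusted over the list alone; Atf3 1.53, Atf4 1.31, Hspa5 0.70, Psat1 0.60), 5 of 15 heat shock genes (6 adjusted over the list alone; Hspa1a 1.38, Dnaja1 0.97, Hsp90ab1 0.63, Dnajb1 0.55) and 5 of 15 matrix genes (5 adjusted over the list alone; Thbs1 1.66, Timp3 1.61, Adamts1 0.70, Col4a1 0.69). Of 16 hypoxia genes 6 rose (8 rises and 1 fall adjusted over the list alone; Ndrg1 0.85, Ddit4 0.66, Aldoa 0.59, Hk1 0.48), of 6 complement and coagulation genes 3 (3 adjusted over the list alone; F3 1.25, Plau 0.76, Thbd 0.40), and of 12 heme and iron genes 2 (3 adjusted over the list alone; Fth1 1.5, Ftl1 1.40). With an estimated correlation the adjusted p of these 6 lists was 0.00491, 0.0343, 0.0347, 0.0178, 0.0361 and 0.0343. Calls were lost for mitochondrial genes (6 of 19 rose; Atp5b 0.94, Uqcrc1 0.67), cytokine and NF-kB genes (4 of 11 rose, 1 fell; Cebpb 1.20, Socs3 0.95), macrophage markers (2 of 7 rose; Cd74 0.69, C1qc 0.47), proximal tubule genes (2 of 24 rose) and loop of Henle genes (Ppp1r1a fell, -0.63), at adjusted p = 0.176, 0.209, 0.101, 0.548 and 0.0566 with an estimated correlation. Skeletal and cardiac muscle (0 of 5 passed), erythroid (0 of 5), lymphocyte (0 of 6) and interferon genes (0 of 5) were not called. In limma 603 genes passed in the average (529 up, 74 down). Within plate C alone 1787 passed (1167 up, 620 down), quantile normalization gave 814 up, 532 down, edgeR 1378 up, 1094 down, and the count was 193 without Sham 1, 333 without RM-HS 3 and 1553 without HS 3. With 1 mean per well run and area 290 passed. With animals unnamed, these p-values are too small. Without Sham 1 the calls of Hspa5, Psat1, Hsp90ab1, Dnajb1, Col4a1, Ndrg1, Ddit4, Aldoa, Hk1, Plau, Thbd, Atp5b, Uqcrc1, Cd74 and C1qc were lost, many of them also without an RM-HS run.

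By area, RM-HS raised Gdf15 (2.79 ± 0.24) and Zfand2a (2.63) most in cortex, where Rgs19 (-1.31) and Clec2j (-1.15) fell most. Neither passed without Sham 1 (-1.04, adjusted p = 0.446, and -0.93, adjusted p = 0.485, in limma), nor Rgs19 without RM-HS 3 and Clec2j without RM-HS 1. At the junction Spp1 (3.71 ± 0.37) and Sat1 (3.52) rose most, Rgs19 (-1.69) and Mat2a (-1.30) fell most, and Havcr1 rose by 2.93 ± 0.22 to 357 ± 139 (SD, n = 8). Of 22 immediate early genes 18 rose there (19 rises and 2 falls adjusted over the list alone; adjusted p = 2.43e-13 with an estimated correlation). In medulla Igfbp1 rose by 3.92 ± 0.27, from 93.7 ± 48 (SD, n = 9) to 1445 ± 196 (SD, n = 9), and Rasd1, a dexamethasone-induced Ras gene, by 3.28, while Clec2j (-1.71) and Sec14l1 (-1.70) fell most. Among the genes with the lowest p of the F test between areas were Havcr1 and Rasd1 (both adjusted p = 1.18e-19), Plin2 (3.48 at the junction and 0.20 in medulla) and Btg2 (3.39 at the junction and 1.41 in cortex). In limma 334 genes passed in cortex (316 up, 18 down), 543 at the junction (455 up, 88 down) and 397 in medulla (317 up, 80 down), and 663 genes passed the F test. The median gene at the junction moved by -0.11. Within plate C alone the counts were 771, 935, 676 and, for the F test, 1090; quantile normalization split the 3 areas 697 up, 403 down, 561 up, 249 down and 498 up, 300 down, and edgeR 913 up, 552 down, 1553 up, 884 down and 1012 up, 761 down. A spread for each area gave 603, 1057 and 768 genes in the 3 areas, and 1 mean per well run and area 48, 240 and 149, with 93 for the F test. Leaving out a well run gave 63 without Sham 1, 97 without RM-HS 3 and 599 without HS 3 in cortex, 275 without Sham 1, 328 without RM-HS 3 and 830 without HS 3 at the junction, 210 without Sham 1 in medulla and, for the F test, 384 without RM-HS 3. Because some ROIs share an animal, these p-values are too small.

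**Figure D2:**
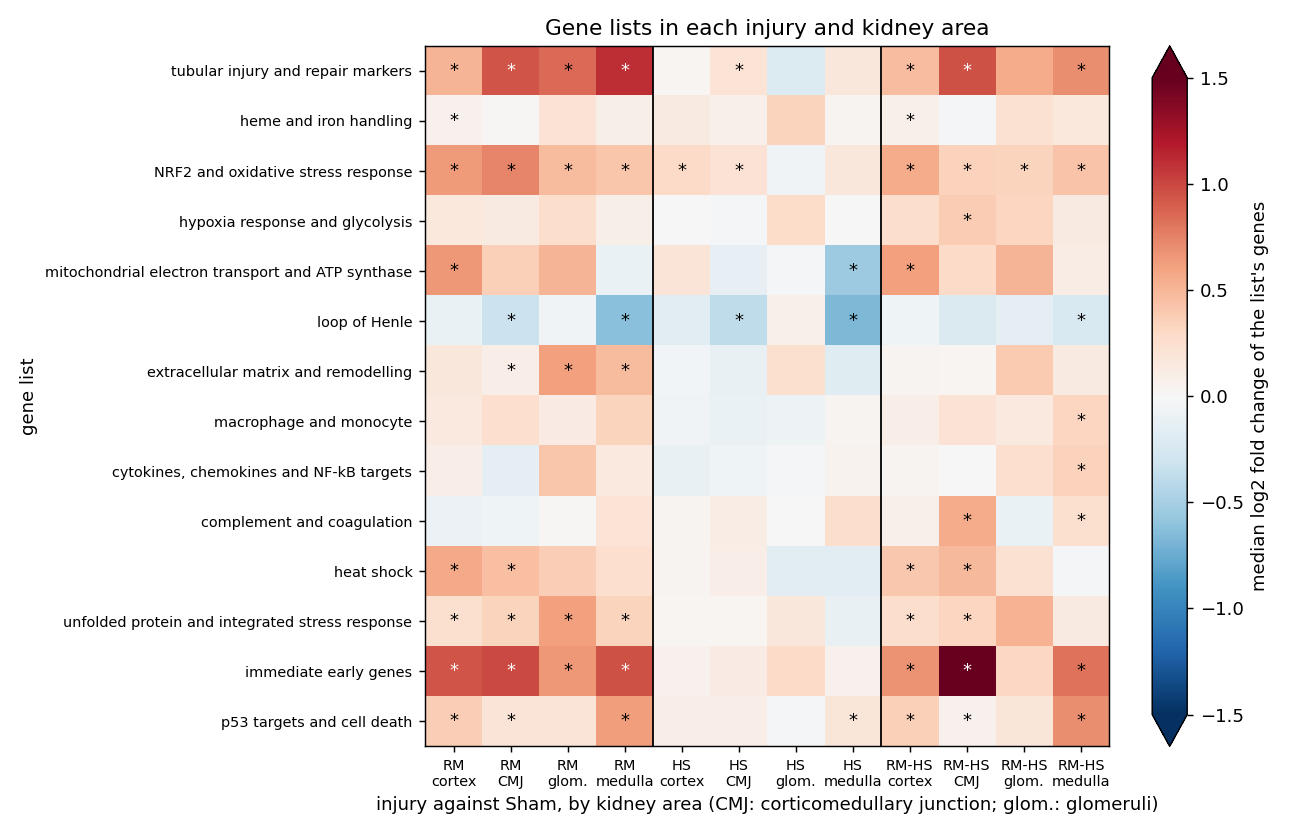
Median log2 fold change of the genes of 14 gene lists (vertical axis) for each injury against Sham in each kidney area (horizontal axis), from blue (lower) to red (higher); asterisks mark lists with an adjusted p under 0.05 with an estimated correlation, and the other 16 of 30 lists had no such mark and are not drawn. Immediate early genes were marked in all 4 areas of RM and in 3 of RM-HS.

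RM-HS against RM asked what HS added to RM. Averaged over areas, Smim22 (0.76 ± 0.17), the circadian repressor gene Nr1d1 (0.76 ± 0.15; adjusted p = 0.00337), Dnase1 (0.70), Ndufa8 of respiratory complex I (0.66), Cyp2d12 (0.55) and Gm10265 (0.55) rose. Clec2j (-1.04 ± 0.20; adjusted p = 0.00186), Gm20792 (-0.90), the dynein light chain gene Dynll1 (-0.62), the elongation factor gene Eef2 (-0.62), Gm7137 (-0.57) and Ube2d2b (-0.55) fell. Havcr1 (-0.17 ± 0.15) and Slc34a1 (0.01 ± 0.17) did not pass (adjusted p = 0.999 and 0.999). Heat shock genes were lower as a list (adjusted p = 0.0438 with an estimated correlation), with 0 of 15 past the threshold over all genes and 5 falls adjusted over the list alone. Hsp90ab1 (-0.47 ± 0.15) and Hspe1 (-0.43 ± 0.15) had the lowest p among them. Lists of injury markers (downward), matrix genes (downward, 3 falls adjusted over the list alone), immediate early genes (downward), complement and coagulation (upward) and neutrophil genes (upward) lost their call, at adjusted p = 0.131, 0.0561, 0.337, 0.0561 and 0.131 with an estimated correlation. At the junction, F3 (1.36 ± 0.23), Plau (1.17) and C3 (1.13) rose among 6 complement and coagulation genes (3 adjusted over the list alone; adjusted p = 3.88e-09 with an estimated correlation) and Dusp5 (1.26), Dusp1 (0.97), Btg2, Fosb and Klf4 among 22 immediate early genes (8 adjusted over the list alone; adjusted p = 1.95e-05 with an estimated correlation). Pck1 (1.79 ± 0.34) and Gpx3 (1.56) rose most there, with Pck1 at 261 ± 160 (SD, n = 8) in RM-HS, and G6pc, the glucose-6-phosphatase gene (-1.79 ± 0.27), and the fructose transporter gene Slc2a5 (-1.28) fell most. In medulla Gm13889 (1.69) and Igfbp1 (1.42 ± 0.26) rose most and Csrp3 (-1.67) and Clec2j (-1.48) fell most. Medullary falls included S100a11 (-0.97) and Anxa2 (-0.87) of 16 injury markers (3 adjusted over the list alone; adjusted p = 0.002 with an estimated correlation) and Timp1 (-0.95) of 15 matrix genes (1 adjusted over the list alone; adjusted p = 0.00239 with an estimated correlation). Each of the 12 genes named for the average lost its call in 2 or more of the fits that left out 1 well run, as did Pck1 and Gpx3 at the junction, while in medulla Clec2j did so without RM 2.

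In limma 20 genes passed for RM-HS against RM in the average (6 up, 14 down), 36 at the junction (22 up, 14 down), 52 in medulla (19 up, 33 down) and 0 in cortex (98 at an unadjusted p under 0.05; 36 in edgeR). With a spread for each area the average gave 0 genes (219 at an unadjusted p under 0.05), against 664 in edgeR, 322 within plate C alone. Leaving out a well run gave 1 without RM 2 or without RM-HS 1, 5 without RM-HS 3, 7 without RM 3, 40 without HS 2 and 207 without HS 3 in the average, 1 without HS 2 or without RM-HS 1, 3 without RM-HS 3, 7 without RM 3 and 8 without HS 3 in cortex, 16 without RM-HS 3, 20 without RM 2, 21 without RM-HS 2 and 77 without HS 3 at the junction and 16 without RM-HS 3, 18 without RM-HS 1, 19 without RM 2, 25 without RM 3, 29 without RM 1 and 117 without HS 3 in medulla. Junction and medulla gave 121 and 203 genes with a spread for each area and 129 and 195 within plate C, and quantile normalization split medulla 40 up, 44 down. With 1 mean per well run and area limma called 0 genes in the average (266 at an unadjusted p under 0.05; edgeR on reads summed in the same way called 62). ROIs that share an animal make these p-values too small.

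RM-HS against HS asked what RM added to HS. Spp1 rose by 2.21 ± 0.43 (adjusted p = 0.000554), Gadd45a by 2.15 ± 0.26, Atf3 by 1.73 ± 0.29, Zfp36 by 1.69 ± 0.22, Zfand2a by 1.66 and Junb by 1.59, while Tsc22d3 (-1.49 ± 0.27) and Pgls (-0.90) fell. Havcr1 (0.73 ± 0.26, adjusted p = 0.237) and Slc34a1 (0.26 ± 0.31, adjusted p = 0.998) did not pass. Of 22 immediate early genes 10 rose (15 adjusted over the list alone), including Klf6 (1.36) and Jun (1.28). Spp1 and S100a11 (1.35) rose among 16 injury markers (9 adjusted over the list alone), Mt2 (1.31), Sod2 (1.10) and Sqstm1 (0.86) among 16 NRF2 genes (4 adjusted over the list alone), Gadd45a and Gadd45g (1.10) among 13 p53 targets (3 adjusted over the list alone) and Dnaja1 (0.84) among 15 heat shock genes (2 adjusted over the list alone). These 5 lists had adjusted p = 7.93e-06, 3.93e-05, 0.0102, 0.000687 and 0.0219 with an estimated correlation. Calls were lost for mitochondrial, matrix and unfolded protein response genes (adjusted p = 0.116, 0.116 and 0.0971 with an estimated correlation), and the median of the mitochondrial list was -0.03 without the plate term. Ftl1 (1.29), Fth1 (1.24), Socs3 (1.30), F3 (1.24), Atf4 (0.90), Atp5b (1.32) and Atp5a1 (1.08) rose too. Without the plate term Atp5b turned to -0.11 (adjusted p = 0.804), and Ftl1 (0.22), Fth1 (0.42), Atp5a1 (0.11) and Pgls (-0.09) did not pass. In limma 96 genes passed (94 up, 2 down), a comparison across plates C and E that rests on the plate term, without which 530 passed. The count was 25 without Sham 1, 40 without HS 2, 41 without RM-HS 3, 46 without RM-HS 2 and 1497 without HS 3; quantile normalization split it 245 up, 83 down and edgeR 282 up, 80 down. With 1 mean per well run and area 11 passed. The p-values, over ROIs not tied to animals, are too small. Calls lost without Sham 1 were those of Spp1, Pgls, S100a11, Ftl1, Fth1, Mt2, Sod2, Sqstm1, Atp5b, Atp5a1, F3 and Dnaja1, and without RM-HS 3 those of Atf4 and Gadd45g (the latter also without Sham 2).

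The interaction asked whether RM and HS together differed from the sum of their separate effects, and 11 genes passed (4 up, 7 down). Thbs1 (-1.65 ± 0.35; adjusted p = 0.011), G6pc (-1.42 ± 0.31), Tsc22d3 (-1.36 ± 0.26), Mt2 (-1.11 ± 0.27), Sqstm1 (-1.03) and Ugdh (-0.97) were lower than the sum, as was Rcan1 (-0.95), a calcineurin regulator. Arhgap24 (1.25 ± 0.29), Ndufa8 (1.12 ± 0.23), Slc16a7 (1.01) and Cyfip2 (0.94) were higher than it. Havcr1 (-0.64 ± 0.25) and Slc34a1 (-0.01 ± 0.30) did not pass (adjusted p = 0.886 and 0.998). Of 16 NRF2 genes Mt2 and Sqstm1 were lower (3 adjusted over the list alone; adjusted p = 0.0292 with an estimated correlation). The lists of immediate early genes and of injury markers lost their call (adjusted p = 0.0621 and 0.0621 with an estimated correlation), as did heme and iron, matrix, unfolded protein response and loop of Henle genes (0.186, 0.186, 0.186 and 0.18 as adjusted p with an estimated correlation). With a spread for each area limma gave 0 genes (207 at an unadjusted p under 0.05; edgeR on reads gave 151, 38 up, 113 down), as did 1 mean per well run and area (270 at an unadjusted p under 0.05; 1 gene in edgeR on reads summed in the same way). Without the plate term 104 passed. The calls of Arhgap24 (0.22, adjusted p = 0.73), Cyfip2 (0.55, adjusted p = 0.107), Tsc22d3 (-0.78, adjusted p = 0.0586) and Ugdh (-0.70, adjusted p = 0.0513) were then lost in limma. With the plate term the HS part of the interaction rests on the single Sham run of plate E for all 11 genes. The interaction gets no value without that run. Tsc22d3 and Ugdh lay near the threshold without the plate term. With 1 well run or another left out all of the 11 but Tsc22d3 and Rcan1 lost their call at least once. Leaving out a well run gave 2 without RM 2, 4 without RM 1 or without RM-HS 2, 5 without RM-HS 1, 7 without RM-HS 3, 57 without HS 2 and 201 without HS 3. As elsewhere, ROIs are not tied to animals and p-values over them are too small.

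Glomeruli stood apart in their spread. Variance between glomerular ROIs was 5.32 times that of cortex, against 0.873 at the junction and 0.804 in medulla. The fit with 1 spread called 1133 genes for RM (889 up, 244 down), led by Thbs1 (2.63 ± 0.31) and Spp1 (2.49) upward and Mmp13 (-1.20) and Abhd15 (-1.17) downward. It called 840 for HS (350 up, 490 down), led by Tsc22d3 (1.84) and Tceal9 (1.80) upward, with Cenpn (-1.64) among the largest falls, and 584 for RM-HS (455 up, 129 down), led by Mt2 (3.14) and Gadd45a (2.17) upward and Rnf207 (-1.26) and Gtpbp6 (-1.18) downward. RM-HS against RM gave 167 (76 up, 91 down), led by Rgs19 (1.37), Olfr1056 (1.31), Zfp36l1 (-1.12) and Tanc2 (-1.07). With a spread for each area the 4 counts were 20, 0, 2 and 0 (for the zeros, 486 and 115 at an unadjusted p under 0.05), and in edgeR 230, 22, 60 and 16. The 20 RM genes of that fit all rose. They included Thbs1 (2.59 ± 0.65), Mt2 (2.42 ± 0.50), the collagen IV gene Col4a1 (2.11 ± 0.47) and Zfp36 (2.03 ± 0.39). Also among them were Cemip2 (1.95 ± 0.36), App (1.86 ± 0.44), Clu (1.82 ± 0.39) and Flt1, a receptor for vascular endothelial growth factor (1.52 ± 0.33). In RM-HS, Mt2 (3.07 ± 0.52) and Gas1 (1.69 ± 0.35) passed in that fit. For these 2 genes 20 of 100 splits of the same ROIs gave as many or more (highest other 8), so that their number is not beyond chance. Quantile normalization split the RM, HS and RM-HS calls 603 up, 351 down, 129 up, 82 down and 371 up, 212 down; within 1 plate they numbered 2216, 225 and 1643. Leaving out a well run gave 562 without Sham 1, 684 without RM 2, 744 without RM 1 and 1948 without HS 3 for RM, 1670 without HS 2 and 2286 without HS 3 for HS, 272 without Sham 1, 313 without RM-HS 3, 332 without RM-HS 2 and 1254 without HS 3 for RM-HS and 31 without RM-HS 2, 37 without RM 2, 79 without RM-HS 1, 94 without RM 3, 98 without Sham 2, 111 without Sham 1, 260 without Sham 3, 281 without RM-HS 3, 388 without HS 2 and 577 without HS 3 for RM-HS against RM. With 5 to 9 ROIs from 3 animals per group, these p-values are too small here too. Calls of single genes were lost for Abhd15 (without RM 3), Rnf207 (RM-HS 2), Gtpbp6 (Sham 1), Rgs19 (RM 2, RM-HS 1 or RM-HS 3), Olfr1056 (RM 2) and Tanc2 (RM 1, RM 2 or RM-HS 2).

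**Figure D3:**
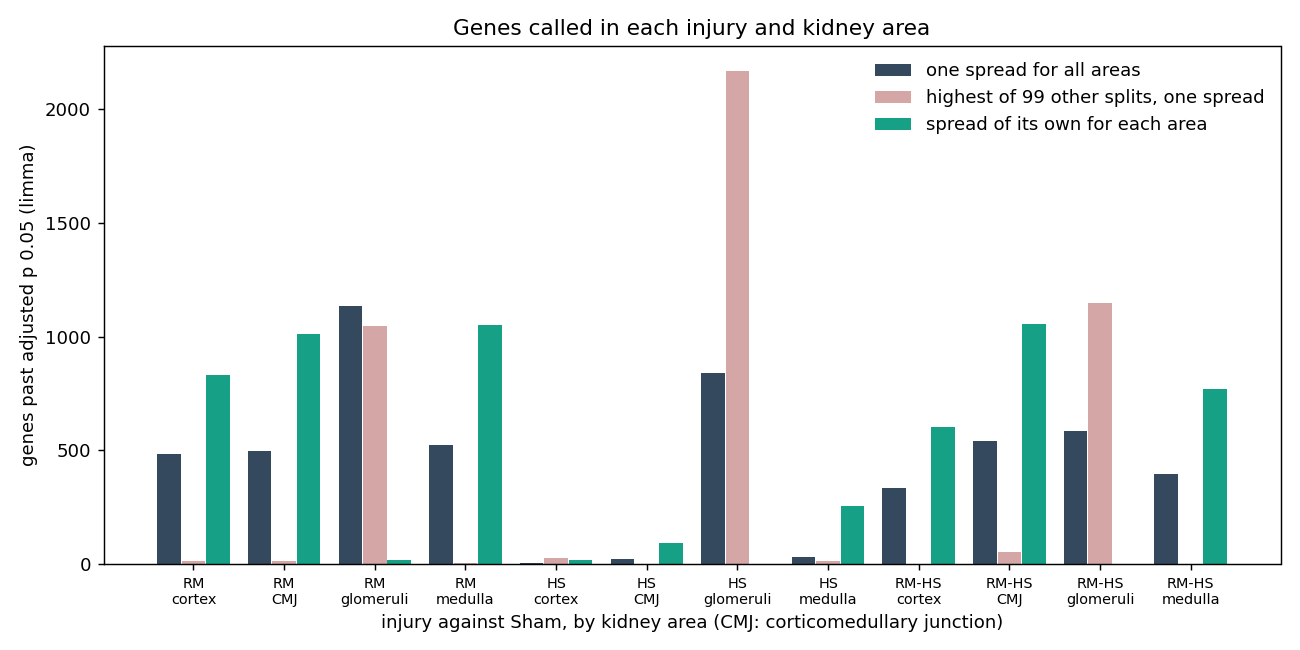
Genes past an adjusted p of 0.05 (vertical axis) for each injury against Sham in each kidney area (horizontal axis): with 1 spread for all areas, the highest of the other 99 splits of the same ROIs under that fit, and with a spread of its own for each area. In HS and RM-HS glomeruli other splits gave up to 2168 and 1147 genes, more than the real 840 and 584.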

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

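What the splits would show was written down after their counts were seen, and the tests on the glomerular calls, on the HS genes and on quantile normalization were likewise chosen after the results were seen; the test on values near the negative probe was written down before its result.

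The effect of an injury differed between areas by an F test for 858 genes in RM, 1198 in HS and 663 in RM-HS. In edgeR on reads summed per well run and area the HS count was 0, with 720 at an unadjusted p under 0.05. Adjusted p in RM was 7.17e-26 for Ppp1r1a, 1.78e-23 for Acly, 4.62e-22 for Havcr1 and 7.43e-22 for Zfand2a. In HS it was 5.72e-10 for Actg1, 2.00e-09 for Cenpn, 3.30e-09 for Tceal9, 5.10e-09 for Fxr2 and 5.66e-08 for Gja5. Of these, Cenpn, Tceal9, Fxr2 and Gja5 passed against Sham in glomeruli alone. There 0 genes passed for HS with a spread for each area, so that these low p rest on the fit with 1 spread. In RM-HS it was 1.18e-19 for Havcr1 and Rasd1, 2.32e-19 for Plin2 and 2.76e-19 for Btg2. The interaction passed for 11 genes: Arhgap24 (1.25), Ndufa8 (1.12), Slc16a7 (1.01), Cyfip2 (0.94), Thbs1 (-1.65), G6pc (-1.42), Tsc22d3 (-1.36), Mt2 (-1.11), Sqstm1 (-1.03), Ugdh (-0.97) and Rcan1 (-0.95). Without the plate term Arhgap24 (0.22, adjusted p = 0.73), Cyfip2 (0.55, adjusted p = 0.107), Tsc22d3 (-0.78, adjusted p = 0.0586) and Ugdh (-0.70, adjusted p = 0.0513) did not pass in limma. With that term the HS part of the interaction rests on the single Sham run of plate E for all 11 genes.

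Single ROIs lay far from the others of their group and area in 16 of 160 Dixon's tests (10 measures in each of 16 combinations of group and area), where chance marks about 1 in 20. Reads were 838546 in RM-HS medulla ROI 6, the negative probe was 30.9 in Sham glomerular ROI 9, and 4064 and 5898 genes exceeded 2 times the negative probe in HS glomerular ROI 1 and RM junction ROI 5. Havcr1 was 122.1 and Igfbp1 145.4 in HS glomerular ROI 5. Slc34a1 was 214.6 in RM junction ROI 5 and 394.7 in RM-HS junction ROI 8. Spp1 was 1493 in HS junction ROI 8 and Mt2 2316 in Sham medulla ROI 7. Igfbp1 was 311.1 in RM cortex ROI 3, 311.9 in RM junction ROI 5 and 203.4 in Sham medulla ROI 4. Pck1 was 65.9 in HS medulla ROI 4, 185.0 in RM-HS glomerular ROI 2 and 41.8 in Sham medulla ROI 2.

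Among 100 splits of the ROIs of 2 groups into groups of the same sizes, 1 (the real one) gave a count as large for these results, in brackets the real count and the highest of the others: RM (733, 3), RM-HS (603, 6), RM-HS against RM (20, 1), RM-HS against HS (96, 86), the interaction (11, 7), RM in cortex (485, 14), RM at the junction (498, 16), RM in glomeruli (1133, 1045), RM in medulla (526, 5), HS at the junction (25, 1), HS in medulla (33, 13), RM-HS in cortex (334, 1), RM-HS at the junction (543, 53), RM-HS in medulla (397, 2), RM-HS against RM at the junction (36, 11), RM-HS against RM in medulla (52, 2), RM between areas (858, 116), HS between areas (1198, 742), RM-HS between areas (663, 207), junction against cortex in Sham (698, 183), glomeruli against cortex in Sham (3388, 1789), medulla against cortex in Sham (1030, 148). For HS in cortex 3 of 100 did (7, 26). For RM in glomeruli the other splits gave a median of 625 genes. In simulated data this fit called 867 unchanged genes there, so that many of the 1133 calls may be false. HS ROIs are on plate E and fitted RM and RM-HS ROIs on plate C, but splits with Sham or HS mix the plates. For all results but RM-HS against RM and the areas of Sham, splits thus have another layout and cannot exclude chance. Splitting single ROIs breaks up animals, so that these splits concern chance among ROIs, under the fit with 1 spread, and not among animals. Chance among ROIs could not be excluded under it for the HS average (15 genes, 68 of 100 splits as large, highest other 168), HS glomeruli (840, 100, 2168), RM-HS glomeruli (584, 93, 1147), RM-HS against RM in glomeruli (167, 68, 321) or cortex (0, 100, 1). Under the fit with a spread for each area it could not be excluded for 9 results, with real count, splits as large and highest other in brackets: the HS average (11, 28, 72), HS in cortex (18, 8, 250), medulla (258, 7, 549) and glomeruli (0, 100, 147), RM-HS in glomeruli (2, 20, 8), RM-HS against RM in the average (0, 100, 0), cortex (0, 100, 4) and glomeruli (0, 100, 1), and the interaction (0, 100, 3). Those 5 real counts of 0 are from limma, with 486, 219, 204, 115 and 207 genes at an unadjusted p under 0.05 and 22, 664, 36, 16 and 151 in edgeR. For the other 19 results 1 of 100 splits, the real one, was as large under that fit too. The calls of RM-HS against RM in the average are thus beyond chance among ROIs under 1 of the 2 fits. The counts of HS in cortex and medulla and of the interaction stood out from the splits under 1 of the 2 fits, with the limit given above. Whole well runs can be split in 10 ways, too few for a share under 0.05: real count, splits as large and highest other were 733, 1 and 322 for RM, 15, 7 and 3150 for HS, 603, 1 and 340 for RM-HS, 20, 2 and 20 for RM-HS against RM, and 96, 5 and 2162 for RM-HS against HS. The splits of 3150 and 2162 genes are many times the real counts, which points to a structure of the samples. Both set HS well run 3 apart from HS runs 1 and 2, and the split of 3150 also parts the Sham runs by plate. The other splits that set HS run 3 apart gave 1107 and 21 genes with Sham and 854 and 471 with RM-HS. In the split of 3150 genes HS run 3 is the only run of its group on plate E. With the plate term it is there compared alone with the other runs of that plate. The splits of 1107 and 21 genes pool it with Sham run 3, and so do not show whether HS run 3 alone accounts for the 3150.

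Glomerular calls against Sham numbered 1133 in RM, 840 in HS and 584 in RM-HS. With a spread for each area 22 of all these were called, and edgeR on reads called 304 of them, so that a larger spread between glomerular ROIs and few reads per ROI both stay as possible explanations of most of them. The 2 Sham glomerular ROIs of fewest reads are argued against, as 1798 of the calls were made without them. No biological explanation was tested for these calls.

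For the 15 genes of HS, values of the lone Sham run on plate E were tested by leaving it out: against the 2 other Sham runs alone, 12 were called in the same direction. That argues against the lone run as the whole source of those 12, but the comparison crosses plates, and 1017 genes passed in it, so that a plate difference may add to it. Log2 fold changes went from 1.51 to 0.64 for Tsc22d3, from -0.98 to -0.40 for Cyfip2 and from 0.57 to 0.30 for Lmo4. The lone run may thus be a large part of the source of these genes. Those of Mt2 (1.75), Sat1 (1.22), Sqstm1 (1.03) and Mt1 (0.90) were not smaller. HS run 3 and Sham run 3 were left out only 1 at a time. The other 3, Arhgap24, Cxcl12 and Pgls, went to a median ratio of -0.117 of the log2 fold change, so that the lone Sham run stays a possible source of these. No value that could have come out otherwise tested a difference between plates. With a plate term the contrast rests on plate E (12 Sham ROIs) and has no weight on plate C. Fold changes within plate E alone are thus near the others by design (median ratio 1.01). There HS and Sham share the plate, and what is mixed with HS is the single Sham run. Of the 15, limma called 0 there (74 genes of all at an unadjusted p under 0.05, 122 in edgeR over both plates). Their SE was larger: Igfbp1 went from 1.52 ± 0.26 to 1.54 ± 0.37 and Mt2 from 1.32 ± 0.22 to 1.34 ± 0.32. Plate C thus enters the 15 calls by way of their spread. Chance among ROIs, as given above, and HS itself stay open as explanations.

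Rises made up 664 of 733 calls in RM. Among as many genes of lowest p under quantile normalization 74.6% rose, between the bounds set for the test. In edgeR, with trimmed-mean scaling, the share was 91.0% (84.2% on summed reads), against 90.6% with the deposited scaling. Among all calls of each fit the share was 63.1% under quantile normalization, 50.1% in edgeR, 59.9% in edgeR on summed reads and 53.3% within plate C alone, and among all genes, called or not, 39.8% rose with the deposited scaling and 44.0% in edgeR. The excess of rises is thus one of the genes of lowest p, and the scaling as a part of its cause is not excluded. As the share under quantile normalization stayed short of the bound of 75%, a part of the excess due to the scaling of the deposited values cannot be told apart from a true excess of rises. Values near the negative probe are argued against as the whole cause, as 92.2% of calls rose among genes with a Sham mean over 4 times the negative probe. The injury stays open as an explanation.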

How the results depend on the processing

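Chosen after the data were seen were the fits with a spread for each area, without 2 Sham glomerular ROIs, in edgeR on reads summed per well run and area, with the 2 pieces of RM-HS run 3 as separate blocks, and of HS against the 2 other Sham runs. All other alternatives were planned. Named genes kept their direction in every alternative that gave them a value, a reversal being counted where the gene passed in either fit, except Atp5b in RM-HS against HS without the plate term (log2 fold change -0.11, adjusted p = 0.804), where the mitochondrial list also reversed (median -0.027, adjusted p = 0.0117), and Arhgap24 in HS against the 2 other Sham runs alone (0.46, adjusted p = 0.113, in the average and 0.25, adjusted p = 0.858, in medulla). Results that the naming rule does not take also turned in that comparison: Pgls in the average (-0.08, adjusted p = 0.697) and Atp5b in medulla (0.13, adjusted p = 0.942). Of 526 results for named genes, 396 had a value under the stricter filter, 395 within 1 plate, 315 without Sham run 3, 80 in the HS comparison with the 2 other Sham runs and 4 in each fit without an HS glomerular ROI. Labels for the 526 were 526 same, 0 weaker, 0 stronger past the threshold with no filter, 524 same, 1 weaker, 1 stronger with a pseudocount of 5, 489 same, 11 weaker, 26 stronger with quantile normalization, 423 same, 103 weaker, 0 stronger with 1 mean per well run and area, and 461 same, 65 weaker, 0 stronger with a spread for each area. Of 50 results for lists, 24 kept and 26 lost their call with an estimated correlation.

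Counts over 1.5 times from the reported ones are given by alternative; injuries alone mean injury against Sham, and the cause was not tested. Within 1 plate and in the means per well run, fewer or averaged samples enter by construction. Within 1 plate: RM 2548, HS 0 (unadjusted 74), RM-HS 1787, RM-HS against RM 322, RM in cortex 952, RM at the junction 942, RM in glomeruli 2216, RM in medulla 907, HS in cortex 0 (unadjusted 44), HS at the junction 0 (unadjusted 83), HS in glomeruli 225, HS in medulla 1, RM-HS in cortex 771, RM-HS at the junction 935, RM-HS in glomeruli 1643, RM-HS in medulla 676, RM-HS against RM in cortex 9, RM-HS against RM at the junction 129, RM-HS against RM in glomeruli 1162, RM-HS against RM in medulla 195, HS between areas 222, RM-HS between areas 1090. Without the well-run block: RM 2967, HS 445, RM-HS 1984, RM-HS against RM 340, RM-HS against HS 850, the interaction 382, RM in glomeruli 1881, HS in cortex 27, HS at the junction 65, HS in glomeruli 1726, HS in medulla 256, RM-HS in glomeruli 1151, RM-HS against RM in cortex 2, RM-HS against RM in glomeruli 435. With 1 mean per well run and area: RM 426, HS 2, RM-HS 290, RM-HS against RM 0 (unadjusted 266), RM-HS against HS 11, the interaction 0 (unadjusted 270), RM in cortex 99, RM at the junction 195, RM in glomeruli 267, RM in medulla 204, HS in cortex 0 (unadjusted 92), HS at the junction 0 (unadjusted 148), HS in glomeruli 519, HS in medulla 1, RM-HS in cortex 48, RM-HS at the junction 240, RM-HS in glomeruli 1.3e+02, RM-HS in medulla 149, RM-HS against RM at the junction 7, RM-HS against RM in glomeruli 28, RM-HS against RM in medulla 4, RM between areas 107, HS between areas 261, RM-HS between areas 93, junction against cortex in Sham 260, glomeruli against cortex in Sham 1505, medulla against cortex in Sham 257. With quantile normalization: RM 1530, HS 27, RM-HS 1346, RM-HS against RM 35, RM-HS against HS 328, RM in cortex 1132, RM at the junction 777, RM in medulla 959, HS in cortex 23, HS in glomeruli 211, HS in medulla 105, RM-HS in cortex 1100, RM-HS in medulla 798, RM-HS against RM in cortex 4, RM-HS against RM in glomeruli 99, RM-HS against RM in medulla 84, HS between areas 636, junction against cortex in Sham 1168, glomeruli against cortex in Sham 2017, medulla against cortex in Sham 1588. In edgeR on reads: RM 3574, HS 122, RM-HS 2472, RM-HS against RM 664, RM-HS against HS 362, the interaction 151, RM in cortex 2046, RM at the junction 2607, RM in glomeruli 230, RM in medulla 2395, HS in cortex 499, HS at the junction 533, HS in glomeruli 22, HS in medulla 334, RM-HS in cortex 1465, RM-HS at the junction 2437, RM-HS in glomeruli 60, RM-HS in medulla 1773, RM-HS against RM in cortex 36, RM-HS against RM at the junction 395, RM-HS against RM in glomeruli 16, RM-HS against RM in medulla 933, junction against cortex in Sham 1328, glomeruli against cortex in Sham 381, medulla against cortex in Sham 2346. In edgeR on reads summed per well run and area: RM 2146, HS 9, RM-HS 1282, RM-HS against RM 62, RM-HS against HS 45, the interaction 1, RM in cortex 247, RM at the junction 855, RM in glomeruli 38, RM in medulla 827, HS in cortex 2, HS at the junction 16, HS in glomeruli 1, HS in medulla 5, RM-HS in cortex 95, RM-HS at the junction 869, RM-HS in glomeruli 9, RM-HS against RM in cortex 2, RM-HS against RM at the junction 62, RM-HS against RM in glomeruli 0 (unadjusted 510), RM between areas 153, HS between areas 0 (unadjusted 720), RM-HS between areas 126, junction against cortex in Sham 281, glomeruli against cortex in Sham 136. Without the plate term: HS 320, RM-HS against HS 530, the interaction 104, HS in cortex 184, HS at the junction 114, HS in glomeruli 1692, HS in medulla 13, RM-HS against RM in glomeruli 101. With the negative probe subtracted: HS 66, RM-HS against RM 48, RM in glomeruli 1755, RM in medulla 299, HS in glomeruli 1376, RM-HS in medulla 214, RM-HS against RM at the junction 11, RM-HS against RM in medulla 18, HS between areas 680, glomeruli against cortex in Sham 2080. With a spread for each area: RM-HS against RM 0 (unadjusted 219), the interaction 0 (unadjusted 207), RM in cortex 830, RM at the junction 1010, RM in glomeruli 20, RM in medulla 1050, HS in cortex 18, HS at the junction 93, HS in glomeruli 0 (unadjusted 486), HS in medulla 258, RM-HS in cortex 603, RM-HS at the junction 1057, RM-HS in glomeruli 2, RM-HS in medulla 768, RM-HS against RM at the junction 121, RM-HS against RM in glomeruli 0 (unadjusted 115), RM-HS against RM in medulla 203, junction against cortex in Sham 1599, glomeruli against cortex in Sham 1217, medulla against cortex in Sham 2590. With the plate A ROI kept: the interaction 7. Without the 2 Sham glomerular ROIs of fewest reads: the interaction 7, RM-HS against RM in glomeruli 265. With the stricter filter: HS in glomeruli 380, RM-HS against RM in glomeruli 56, HS between areas 751, glomeruli against cortex in Sham 1734. Against the 2 other Sham runs: HS 1017, HS in cortex 530, HS at the junction 246, HS in glomeruli 1928, HS in medulla 13.

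Leaving out 1 well run or 1 HS glomerular ROI gave these lowest and highest counts: RM 294 to 2232, HS 12 to 657, RM-HS 193 to 1553, RM-HS against RM 1 to 207, RM-HS against HS 25 to 1497, the interaction 2 to 201, RM in cortex 137 to 789, RM at the junction 238 to 761, RM in glomeruli 562 to 1948, RM in medulla 292 to 785, HS in cortex 5 to 146, HS at the junction 13 to 73, HS in glomeruli 684 to 2286, HS in medulla 7 to 354, RM-HS in cortex 63 to 599, RM-HS at the junction 275 to 830, RM-HS in glomeruli 272 to 1254, RM-HS in medulla 210 to 582, RM-HS against RM in cortex 0 to 8, RM-HS against RM at the junction 16 to 77, RM-HS against RM in glomeruli 31 to 577, RM-HS against RM in medulla 16 to 117, RM between areas 468 to 1134, HS between areas 944 to 1780, RM-HS between areas 384 to 877, junction against cortex in Sham 481 to 790, glomeruli against cortex in Sham 2293 to 3750, medulla against cortex in Sham 535 to 1224. The most genes for the RM, HS and RM-HS averages came without HS well run 3. Without Sham well run 3, HS against Sham, RM-HS against HS and the interaction got no value, since no Sham ROI was left on plate E. Taking the 2 pieces of RM-HS run 3 as separate blocks moved no count by over 1.5 times (RM-HS 657, RM-HS against RM 26). Within 1 plate, RM-HS against HS and the interaction got none.

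Glomeruli had the fewest reads of the 4 areas, with a median of 93104 per ROI. In simulated data a 1.5-fold change was found for 9 of 100 genes in glomeruli with a spread for each area and for 83 of 100 in the average over areas, which pools more ROIs. No other single area was simulated, and depth was not separated from the larger variance of glomerular ROIs.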

Other observations

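Both hypotheses here were tested after the values that prompted them had been seen. By well run, Mt2 in HS cortex averaged 1401, 1302 and 5775 in HS runs 1, 2 and 3, Igfbp1 76.9, 122 and 545, and the proximal tubule genes Pck1 921, 498 and 3909 and Slc34a1 311, 220 and 1078. The 10 most abundant genes took 11.6% to 12.1% of the reads of run 3 there and 5.43% to 7.4% of those of runs 1 and 2, so that run 3 stood apart in more than the genes that rose. In Sham cortex Pck1 averaged 384, 559 and 1349 in Sham runs 1, 2 and 3, of which run 3 is on plate E. At the junction of HS Havcr1 averaged 84.5, 145 and 143, Spp1 83.7, 183 and 825 and Pck1 209, 116 and 172. Each value is a mean of 3 ROIs, and whether a run is an animal is not given in the labels.

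Tsc22d3, Zbtb16, Igfbp1, Mt1, Mt2, Sat1 and Dusp1, which rose in HS, include known targets of glucocorticoids. A list of 21 other targets, 14 of them measured, was written down before it was tested. Its median log2 fold change in HS was 0.33, with 11 of 14 positive, 0 past the threshold one by one in limma (4 at an unadjusted p under 0.05; 5 in edgeR), and p = 1.47e-07 by cameraPR of limma (0.000235 with an estimated correlation). The list was also higher in RM (adjusted p = 0.00468), in RM-HS (adjusted p = 3.62e-06) and in RM-HS against RM (adjusted p = 0.0055) by cameraPR of limma, and in limma 3 of its members rose and 1 fell in RM, 8 rose and 1 fell in RM-HS and 0 passed in RM-HS against RM (2 at an unadjusted p under 0.05; 2 in edgeR). Of the 14 measured, 6 are also on other lists of the report, and values of some, such as Cebpb and Cebpd in RM, had been seen before. Without HS run 3 the 7 genes still passed in HS, with log2 fold changes at 55.4% (Mt2) to 74.6% (Dusp1) of those with all runs. HS values rest on the lone Sham run of plate E, without which the list was not retested. A glucocorticoid-type response may contribute to the HS rises. Hormones were not measured, the list does not set HS apart from RM, and ROIs are not tied to animals.

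Clec2j and Gm20792, which fell in RM-HS, have no rat gene of the same symbol in the rat gene table used. Among the 14 falls of RM-HS against RM, 4 (28.6%) lacked a rat symbol against 6.83% of other genes (Fisher exact p = 0.0126; adjusted p = 0.0202 over 8 tests). The share was 18.8% among falls and 1.96% among rises of RM against Sham (adjusted p = 0.00143 and 2.79e-08), and 24.3% and 2.08% for RM-HS against Sham (adjusted p = 4.57e-06 and 1.93e-06). Rises of RM-HS against RM did not show the same direction: 2 of 6 (33.3%) lacked a rat symbol (adjusted p = 0.0782). In HS it was 1 of 11 rises and 0 of 4 falls (adjusted p = 0.62 and 1). Falls of such probes may be of background or cross-hybridisation, not of a rat transcript. Background alone is argued against for Clec2j and Gm20792 (Sham means 653 and 201, negative probe 21.7). A differing symbol does not show that a gene is absent, and sequence was not tested.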
